A study of Homo sapiens with 60 samples.

How the data were processed

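HT29 colorectal adenocarcinoma cells were treated for 24 h, and messenger RNA libraries made from total RNA were sequenced with reads of 100 bp. The labels name no poly(A) selection. Per the labels, 60 libraries formed 20 groups of 3 libraries: vehicle, wortmannin, and 6 water extracts at 3 doses each. The same deposited table held 210 columns of other samples, which were not used. The series text also mentions ethanol extracts and says that samples with little RNA had been left out by the submitters.

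The deposited values are expected counts per gene, made by the authors with FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 on GRCh38 (hg38). They were not scaled between libraries, and the annotation release is not stated in the sources used here. Of all values 8.75% were not whole, as RSEM divides reads between genes, and they were rounded to whole counts. The table has 60675 Ensembl genes, of which 57055 occur in GENCODE release 29. A separate reference of gene names gave a symbol to 56558, and the name in release 29 was used where it had none. Gene positions are those of release 29 on GRCh38. Libraries held 11.1 to 34.4 M counts (M, 1e6; median 23.4 M). The smallest chi-square per gene between any 2 libraries was 2.06 (2.35 within a group), so no library was a copy of another.

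Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling and the filterByExpr filter (16609 genes left). Robust quasi-likelihood tests had 1 coefficient per group over all 60 libraries (40 residual degrees of freedom, common dispersion 0.004433). Log2 changes are those of this fit. Log2 CPM values with a prior count of 2 served only the list tests, the principal components and the correlations of replicate numbers. Each of the 28 comparisons was adjusted by the Benjamini-Hochberg method over its own genes, and a gene was called below 0.05. The comparisons were each treatment against vehicle, high against low dose of each extract, and ginger against fresh ginger at each dose. Added after the data were seen were high against medium and medium against low dose, and differences between extracts in their high-against-low change, tested as interaction terms. Values after ± on a log2 change are approximate standard errors, the absolute change divided by the square root of its quasi-likelihood F statistic. They were not taken from the fit itself, and need not combine between contrasts as fitted errors would. For CYP1A1, high against low dose, they were 0.125 (Scutellariae Radix), 0.135 (Coptidis Rhizoma) and 0.217 (difference between these extracts). Intervals rest on these errors and cover a nominal 95%. Levels are counts per 1e6 (CPM), mean and standard deviation of 3 libraries.

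Of 34 gene lists of receptor and stress pathways, metabolism, cell cycle, signalling, and intestinal and other cell-type markers, those with at least 4 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated. Each list's members were also adjusted over the list alone. Groups, the 28 comparisons, lists, alternatives and the rule for naming genes were set before the data were examined. By that rule, genes that were called, had at least 5 CPM in the group with the higher mean and had all libraries of a group on the same side of all libraries of the other were ranked by change: the 8 largest in each direction for wortmannin and high doses, 5 for high against low dose and for ginger against fresh ginger, and 3 for medium and low doses. Up to 4 tested members of each list were added by smallest p, with no minimum CPM. Genes of the added comparisons were chosen after their values were seen. A gene that met the rule is not reported here.

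Alternatives were the DESeq2 size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, only the libraries compared, the replicate number as a block, leaving out each library in turn, a linear trend on log10 dose, an estimated correlation for lists, and similarity over genes called in either extract. An alternative without the 4 libraries that stand apart on the second principal component was chosen after seeing the data. Replicate numbers are shared between groups in the labels. After group means were removed, all correlations of matched numbers were above 0.1 in 1 of 28 comparisons (fresh ginger low against vehicle), in which the block gave 0 genes, as did the fit without it. Correlations ranged from -0.37 to 0.34. Most of the comparisons set a treatment against vehicle, which is in another set, so they could not show sharing by replicate number inside a set. The block was 1 effect of each number over all groups and could not take up such sharing. The closest libraries of different groups included pairs of the same set and number and pairs of different numbers, so it stays open.

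The fit was tested on counts simulated for all 60 libraries from 1 shared profile, with 200 genes changed in Scutellariae Radix high. It recovered 73.1% of genes changed by a log2 of 0.5, 92.5% at 1 and 100% at 2, with 9 false calls. It called 0 genes where nothing was changed (camera: 0 of 50 random lists). The simulated libraries held no sets and none that stand apart, so false calls from such structure in the real data were not measured.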

Results

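HT29 cells, an established line from a human colorectal adenocarcinoma, were profiled by RNA sequencing 24 h after addition of water extracts of 6 herbal medicines. The 60 libraries formed 20 groups of 3. Of the extracts, 5 were given at 500, 100 and 20 µg/mL: Zingiberis Rhizoma Recens (called fresh ginger below), Zingiberis Rhizoma (called ginger below), Pinelliae Tuber, Scutellariae Radix and Zizyphi Fructus. Coptidis Rhizoma was given at 290, 58 and 11.6 µg/mL, its top dose being the one that inhibited the cells by 20%. These doses are called high, medium and low. The remaining groups received vehicle (DMSO, 0.1% in the sample labels and 2% in the series text) or 10 µM wortmannin, an inhibitor of phosphoinositide 3-kinase (PI3K) used as the positive control. In every comparison 16609 genes were tested with edgeR, each adjusted for its own number of genes at 0.05. If no gene changed, 830 of them would have an unadjusted p under 0.05 by chance. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between libraries, which may be technical. All titles name the same batch, and the sample descriptions hold only codes. Libraries whose codes share the first part (A1, 1, 2, 3 or 4) are called a set here. The labels do not say what that part stands for, or whether A1 and 1 differ in handling. By the codes, vehicle (A1) and wortmannin (1) are each alone in a set and both gingers share 1 set. Pinelliae Tuber is with Scutellariae Radix, and Coptidis Rhizoma with Zizyphi Fructus. A difference from vehicle is therefore also a difference between sets, and perhaps in DMSO, since the labels do not say whether the extracts held any, while high against low dose of an extract lies inside 1 set and uses no vehicle. Only 4 libraries stood apart from the rest on the second principal component (8.5% of the variance): vehicle replicate 1, fresh ginger low replicate 1, ginger high replicate 2 and Zizyphi Fructus high replicate 3. In that order, 6.39, 5.85, 5.90 and 7.57% of their counts came from ribosomal-protein genes. Outside Coptidis Rhizoma high, the other libraries had at most 5.41%. Whether this is related was not tested. The number of genes called ranged from 0 to 8930 between groups, as the plot of genes called per group shows.

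**Figure D1:**
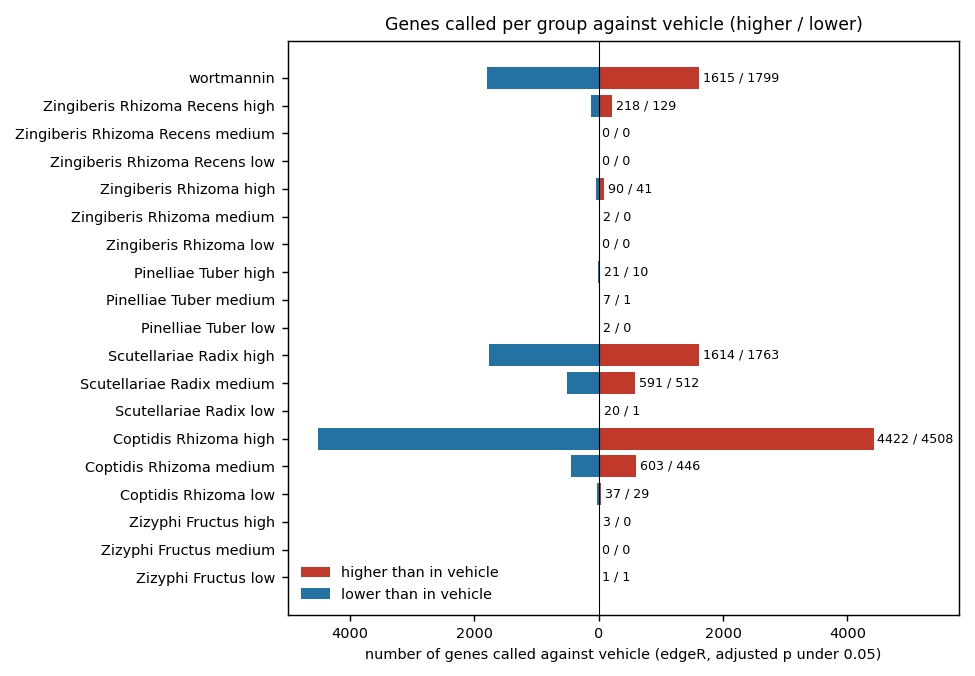
Genes called higher or lower than vehicle in each treated group (edgeR, adjusted p below 0.05, n = 3 libraries per group). The 19 groups share the same 3 vehicle libraries.

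Wortmannin raised genes of the interferon response and lowered genes of mitosis. IFI44L, an interferon-induced gene of antiviral defence, rose 13.3-fold, and the antiviral GTPase MX1 rose 5.93-fold. OAS2, which makes the activator of RNase L, rose 7.23-fold, and IFIT1, which binds foreign RNA, rose 5.27-fold. Cyclin B1 (CCNB1) and the kinase PLK1, which drive entry into and passage through mitosis, fell, and so did securin (PTTG1), a regulator of chromosome separation. IFI44L (ENSG00000137959, chromosome 1: 78619922-78646145, GRCh38, GENCODE 29) went from 1.28 ± 0.251 to 16.6 ± 1.99 counts per 1e6 (CPM, mean ± SD). Its log2 change was 3.73 ± 0.27 (approximate SE, adjusted p = 3.28e-15). For MX1 the log2 change was 2.57 ± 0.14 and for IFIT1 2.40 ± 0.13 (adjusted p = 7.93e-20 for each). All 21 tested interferon genes rose, also when adjusted over the list alone, and the list was called (camera adjusted p = 1.56e-44; adjusted p = 6.4e-06 with an estimated correlation). Of 21 mitosis genes, 19 fell (21 adjusted over the list alone, camera adjusted p = 4.35e-35, and 4.57e-06 with an estimated correlation). CCNB1 decreased by 0.96 ± 0.06 on the log2 scale (adjusted p = 3.32e-17), PLK1 by 0.85 ± 0.05 (adjusted p = 7.93e-20) and PTTG1 by 1.19 ± 0.13 (adjusted p = 1.73e-09).

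Some genes under FOXO control, which PI3K signalling holds down, rose with wortmannin as well, though the list was not called with an estimated correlation. TXNIP, a brake on glucose uptake, rose with a log2 change of 0.75 ± 0.06 (adjusted p = 9.3e-15), the insulin receptor INSR with 0.70 ± 0.09 (adjusted p = 3.98e-08) and its adaptor IRS2 with 0.48 ± 0.08 (adjusted p = 8.2e-06). Asparagine synthetase (ASNS), a target of the amino-acid stress factor ATF4, fell by 0.76 ± 0.06 (adjusted p = 1.43e-13). The intestinal stem-cell receptor LGR5 rose with 0.67 ± 0.06 (adjusted p = 9.36e-13). In the FOXO and PI3K list 8 of 20 genes rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.000338; adjusted p = 0.0974 with an estimated correlation), and in the ATF4 list 11 of 23 fell (12 adjusted over the list alone, camera adjusted p = 3.94e-05; adjusted p = 0.0949 with an estimated correlation). Chaperones of the endoplasmic reticulum fell in 9 of 16 cases and rose in 1 (9 and 2 adjusted over the list alone, camera adjusted p = 9.13e-06; adjusted p = 0.0326 with an estimated correlation), with HSP90B1 down by 0.49 (adjusted p = 1.5e-12). Lower too were 15 of 24 nuclear genes of oxidative phosphorylation (22 adjusted over the list alone, camera adjusted p = 3.3e-08; adjusted p = 0.234 with an estimated correlation) and 9 of 20 MYC targets (13 adjusted over the list alone, camera adjusted p = 0.000466; adjusted p = 0.0974 with an estimated correlation). In all, 3414 genes were called, 1615 higher (142 by at least a doubling) and 1799 lower (32 by at least a halving). Without vehicle replicate 1 the count was 2114.

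Fresh ginger at the high dose raised enzymes that detoxify reactive compounds. AKR1C2 and AKR1B10, aldo-keto reductases that dispose of carbonyls, rose 3.10-fold and 2.28-fold. The aldehyde dehydrogenase ALDH3A1, the rate-limiting enzyme of glutathione synthesis GCLC and the cystine carrier SLC7A11 rose, and so did the neutrophil attractant CXCL8, 2.02-fold. REG4, a secreted lectin, and AGR2, which folds mucins, both products of goblet cells, fell. AKR1C2 (ENSG00000151632, chromosome 10: 4987400-5018031) went from 10.3 ± 1.35 to 31.4 ± 0.980 CPM (log2 change 1.63 ± 0.12, adjusted p = 2.03e-14). For AKR1B10 the log2 change was 1.19 ± 0.07 (adjusted p = 1.09e-17), for ALDH3A1 0.99 ± 0.10 (adjusted p = 1.77e-10), for CXCL8 1.01 ± 0.15 (adjusted p = 6.28e-06) and for REG4 -0.77 ± 0.10 (adjusted p = 3.44e-07). Of 20 targets of the antioxidant factor NRF2, 16 rose (16 adjusted over the list alone, camera adjusted p = 1.48e-41, and 1.75e-07 with an estimated correlation), as did 5 of 9 targets of the aryl hydrocarbon receptor (AhR, 7 adjusted over the list alone, camera adjusted p = 3.54e-10). Of 17 NF-kB targets 3 rose (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00121; adjusted p = 0.0146 with an estimated correlation), and of 12 goblet-cell genes 5 fell (5 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000357; adjusted p = 0.00273 with an estimated correlation). Interferon genes were lower as a list (1 of 21 fell, 8 adjusted over the list alone, camera adjusted p = 3.94e-06; adjusted p = 0.154 with an estimated correlation). The AhR list holds NFE2L2, which encodes NRF2, along with NQO1 and ALDH3A1. A rise of that list, here or with another extract, need not be separate from that of the NRF2 targets. AKR1C1 and AKR1C2 are near-identical in sequence, so reads may have been shared between them. The call held 347 genes, 218 higher and 129 lower. Without the low-count filter it held 1127, of which 38.8% were higher. Without vehicle replicate 1 it held 128, and without replicate 2 or 3 of the extract 160 or 156.

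Inside the set, high against low fresh ginger gave the same enzymes. AKR1C2 differed by a log2 of 1.51 ± 0.12 (adjusted p = 6.86e-13), AKR1B10 by 1.21 (adjusted p = 6.88e-18), and REG4 by -0.72 (adjusted p = 4.58e-06). Of the NRF2 targets 17 were higher (17 adjusted over the list alone, camera adjusted p = 1.45e-45, and 2.88e-08 with an estimated correlation), with 6 AhR targets (7 adjusted over the list alone, camera adjusted p = 6.54e-14) and 6 NF-kB targets (6 adjusted over the list alone, camera adjusted p = 2.86e-05). In this contrast 297 genes were called, 200 higher and 97 lower. Without the low-count filter 565 were called, of which 42.5% were higher. A fit of the 6 libraries alone called 23, and a linear trend on log10 dose 32. The count was 123, 152, 118 and 156 without low replicate 1, high replicate 2, high replicate 3 and low replicate 3, and 1305 without low replicate 2. At the medium and low doses edgeR called 0 genes against vehicle, and at the low dose 1 without low replicate 1. There were 1468 and 747 genes at unadjusted p under 0.05, where 830 are expected by chance. DESeq2 called 0 and 0 at these doses, and edgeR without the low-count filter 407 and 117. High against medium gave 76 genes, and medium against low gave 0.

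Ginger at the high dose raised the same detoxifying enzymes and raised chemokines. CXCL8 rose 2.48-fold and the related attractant CXCL1 rose too. AKR1C2, AKR1B10 and ALDH3A1 rose, as did CYP1A1 (3.67-fold) and CYP1B1, oxidases under AhR control. SLC6A20, a proline carrier, CREB3L1, a factor that promotes secretion, and the superoxide-producing oxidase NOX1 fell. CXCL8 (ENSG00000169429, chromosome 4: 73740506-73743716) went from 4.00 ± 0.475 to 9.88 ± 0.735 CPM (log2 change 1.31 ± 0.14, adjusted p = 6.92e-09), and CXCL1 changed by 1.60 (adjusted p = 5.93e-06). The log2 changes were 1.14 ± 0.12 for AKR1C2 (adjusted p = 3.99e-09), 0.95 for AKR1B10 (adjusted p = 7.55e-14) and 1.88 ± 0.26 for CYP1A1 (adjusted p = 4.32e-06). SLC6A20 fell by 0.61 ± 0.09 (adjusted p = 1.91e-05), CREB3L1 by 0.51 ± 0.07 (adjusted p = 4.32e-06) and NOX1 by 0.47 ± 0.09 (adjusted p = 0.00125). Of the NRF2 targets 15 of 20 rose (16 adjusted over the list alone, camera adjusted p = 8.02e-52, and 5.67e-09 with an estimated correlation), of the AhR targets 6 of 9 (6 adjusted over the list alone, camera adjusted p = 1.56e-17) and of the NF-kB targets 5 of 17 (8 adjusted over the list alone, camera adjusted p = 5.77e-10). Of 131 genes called, 90 were higher and 41 lower. Without the low-count filter 244 were called, of which 46.3% were higher. The count of 131 fell to 68, 68 and 87 without vehicle replicates 1, 2 and 3, and to 84 and 66 without replicates 1 and 2 of the extract. A fit of the 6 libraries alone called 10 genes, and SLC6A20 and NOX1 were lost in it (adjusted p = 0.136 for each, the highest over all alternatives).

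High against low ginger gave 152 genes, 86 higher and 66 lower, led by AKR1C2 (1.29, adjusted p = 2.14e-10), AKR1B10 (0.99, adjusted p = 1.77e-14) and CXCL8 (0.99, adjusted p = 8.7e-06). Without low replicate 1, high replicate 2 or low replicate 2 the count was 63, 79 or 76. NRF2 targets were higher in 17 cases (20 adjusted over the list alone, camera adjusted p = 4.52e-47, and 1.92e-08 with an estimated correlation). Interferon genes were lower in 4 of 21 cases (12 adjusted over the list alone, camera adjusted p = 1.06e-12; adjusted p = 0.016 with an estimated correlation). At the medium dose CXCL8 (0.85 ± 0.14) and the nuclear long noncoding RNA NEAT1 (0.42 ± 0.07) rose (adjusted p = 0.00495 for each), 2 genes in all, with 2133 at unadjusted p under 0.05. CXCL8 was lost without vehicle replicate 2 (adjusted p = 0.0534) and without replicate 1 of the dose (0.0582). Its adjusted p ranged from 3.61e-07 to 0.0978 over the alternatives that gave one, which the DESeq2 test did not. NEAT1 was lost without vehicle replicate 1 (0.339) or replicate 1 of the dose (0.0969), with 1.74e-08 to 0.339 over all alternatives. Without the 4 libraries that stand apart NEAT1 was lost too (0.0657). Like RGS2 below, NEAT1 differed between vehicle and the mean of the 6 low-dose groups, which is not a test of each extract. The count was 1, 1 and 0 without vehicle replicate 1, vehicle replicate 2 and replicate 1 of the dose. At the low dose 0 genes were called (1888 at unadjusted p under 0.05; 1 by DESeq2, 602 by edgeR without the low-count filter). High against medium gave 41 genes and medium against low 0.

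The gingers were also compared with each other at each dose, inside their shared set. For CYP1A1 the log2 difference at the high dose was 0.99 in favour of ginger (adjusted p = 0.346). Its unadjusted 95% interval lay wholly on the side of ginger and reached 1.472. For AKR1C2 the difference was -0.49 (unadjusted interval -0.712 to -0.270, adjusted p = 0.258). Neither gene was called after adjustment over all genes tested, so differences of these sizes remain open. edgeR called 0, 0 and 0 genes at the high, medium and low doses, with 358 at the low dose without fresh ginger low replicate 2. There were 1235, 429 and 1309 genes at unadjusted p under 0.05, where 830 are expected by chance. DESeq2 called 0, 0 and 0. Without the low-count filter edgeR called 159, 55 and 229, without the 4 libraries that stand apart 4 at the high dose, and with the replicate block 1 at the high and 1 at the medium dose. As a list, NRF2 targets were lower in ginger at the high dose (0 genes, 5 adjusted over the list alone, camera adjusted p = 3.22e-05; adjusted p = 0.195 with an estimated correlation), and NF-kB targets were higher at the medium dose (0 genes, 3 adjusted over the list alone, camera adjusted p = 0.00317; adjusted p = 0.0356 with an estimated correlation).

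Pinelliae Tuber at the high dose raised chemokines and lowered genes of lipid synthesis. CXCL1 rose 3.26-fold, CXCL8 2.16-fold and CCL20, which attracts dendritic and Th17 cells, 4.38-fold, and the sterol exporter ABCG1 rose. ACSS2, which makes acetyl-CoA from acetate, and RGS2, a brake on G-protein signalling, fell. CXCL1 went from 1.44 to 4.75 CPM (log2 change 1.70 ± 0.22, adjusted p = 4.95e-06), CXCL8 from 4.00 to 8.56 CPM (1.11 ± 0.14, adjusted p = 4.5e-06), and CCL20 changed by 2.13 ± 0.39 (adjusted p = 0.00221). ABCG1 rose with 0.79 ± 0.11 (adjusted p = 1.99e-05), ACSS2 fell by 0.51 ± 0.07 (adjusted p = 1.69e-05) and RGS2 by 0.49 ± 0.08 (adjusted p = 0.000818). ABCG1 and RGS2 were not called between the high and low doses, and RGS2 also differed between vehicle and the mean of the 6 low-dose groups. Of 17 NF-kB targets 5 rose (9 adjusted over the list alone, camera adjusted p = 1.9e-12, and 1.59e-06 with an estimated correlation), and of 18 cholesterol genes 2 fell (11 adjusted over the list alone, camera adjusted p = 2.11e-14, and 0.000376 with an estimated correlation). Squalene epoxidase (SQLE) fell by 0.20 (adjusted p = 0.00389) but was not called without the low-count filter (0.0982), without vehicle replicate 3 (0.0675) or without replicate 3 of the extract (0.0957; 1.99e-05 to 0.399 over all alternatives). SQLE too was not called between the high and low doses. In total 31 genes were called against vehicle, 21 higher and 10 lower. Without the low-count filter 637 were called, of which 37.2% were higher. A fit of the 6 libraries alone called 9, of which 44.4% were higher. The count was 14 and 17 without vehicle replicates 1 and 3, and 55, 17 and 12 without replicates 1, 2 and 3 of the extract.

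Between high and low Pinelliae Tuber 7 genes differed, 6 higher and 1 lower. CXCL8 was higher with 1.14 ± 0.14 (adjusted p = 2.5e-06), CXCL1 with 2.17 (adjusted p = 8.61e-08) and ACSS2 lower with -0.42 (adjusted p = 0.00124). NF-kB targets were higher in 4 of 17 cases (9 adjusted over the list alone, camera adjusted p = 3.4e-29, and 1.91e-11 with an estimated correlation), and cholesterol genes were lower as a list (0 genes, 9 adjusted over the list alone, camera adjusted p = 1.22e-15, and 0.000154 with an estimated correlation). High against medium gave 6 genes and medium against low 0. Against vehicle, the medium dose gave 8 genes (7 higher, 1 lower), among them the DNA-repair partner EME2 (0.54, adjusted p = 0.00772), ABCG1 (0.53, adjusted p = 0.0485) and NEAT1 (0.36, adjusted p = 0.0349). All 3 were lost without vehicle replicate 1 (adjusted p = 0.142, 0.541 and 0.541), vehicle replicate 3 (0.0589, 0.109 and 0.0921) and replicate 3 of the dose (0.823 for each, the highest over all alternatives). ABCG1 and NEAT1 were also lost without vehicle replicate 2 (0.177 and 0.0661) and replicate 2 of the dose (0.259 for each). The low dose gave 2, EME2 (0.57 ± 0.09, adjusted p = 0.00311) and the protease PRSS53, named after its value was seen. EME2 at the low dose was lost without vehicle replicate 1 or 3 (adjusted p = 0.0727 and 0.0709) and without its own replicate 3 (0.161; 2.5e-12 to 0.161 over all alternatives, with 0.105 without the 4 libraries). The medium count was 0, 1 and 0 without vehicle replicates 1, 2 and 3, and 14, 1 and 0 without its own replicates 1, 2 and 3. The low count was 0, 10 and 0 without vehicle replicates 1, 2 and 3, and 7 and 0 without its own replicates 1 and 3.

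Scutellariae Radix at the high dose raised targets of AhR, the receptor for flat aromatic ligands, together with antioxidant, amino-acid and sterol genes. CYP1A1 rose 100-fold and CYP1B1 5.90-fold. SLC7A11 rose 2.98-fold, ASNS 1.92-fold and SQLE, an early enzyme of sterol synthesis, 1.52-fold. The interferon factor IRF9 and MX1 fell, and so did NOX1, CD200, a surface protein that restrains immune cells, and ATOH1, the factor that specifies secretory cells. CYP1A1 (ENSG00000140465, chromosome 15: 74719542-74725610) went from 0.563 ± 0.120 to 57.0 ± 2.02 CPM (log2 change 6.64 ± 0.16, adjusted p = 2.23e-35), and CYP1B1 changed by 2.56 ± 0.08 (adjusted p = 3.28e-29). The log2 changes were 1.58 ± 0.07 for SLC7A11 (adjusted p = 1.74e-23), 0.94 ± 0.06 for ASNS (adjusted p = 3.94e-18), 0.60 ± 0.04 for SQLE (adjusted p = 5.84e-18), -1.08 ± 0.13 for IRF9 (adjusted p = 3.78e-09), -1.36 ± 0.17 for MX1 (adjusted p = 1.35e-08) and -2.15 ± 0.10 for NOX1 (adjusted p = 3.15e-23). In total 3377 genes were called, 1614 higher (107 by at least a doubling) and 1763 lower (261 by at least a halving).

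By list, 8 of 9 AhR targets rose with the high dose of Scutellariae Radix (9 adjusted over the list alone, camera adjusted p = 8.89e-22, and 3.12e-11 with an estimated correlation) and 18 of 20 NRF2 targets rose (18 adjusted over the list alone, camera adjusted p = 1.85e-38, and 2.16e-07 with an estimated correlation). All 18 cholesterol genes rose (18 adjusted over the list alone, camera adjusted p = 1.39e-26, and 1.09e-06 with an estimated correlation), with 15 of 23 ATF4 targets (16 adjusted over the list alone, camera adjusted p = 3.21e-18, and 0.000139 with an estimated correlation). Hypoxia genes such as the glucose carrier SLC2A1 (0.74 ± 0.04, adjusted p = 1.53e-22) rose in 12 of 21 cases (13 rose and 1 fell adjusted over the list alone, camera adjusted p = 5.27e-10, and 0.000464 with an estimated correlation). Immediate-early genes such as EGR1 and FOS rose in 11 of 16 cases and fell in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 2.35e-08, and 0.0032 with an estimated correlation). Of 21 interferon genes 16 fell (19 adjusted over the list alone, camera adjusted p = 3.49e-12; adjusted p = 0.0139 with an estimated correlation). Of 13 Wnt and stem-cell genes 7 fell, with LGR5 and EPHB3 among them (7 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.000644; adjusted p = 0.0325 with an estimated correlation). FOXO and PI3K genes fell in 11 of 20 cases and rose in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.000198; adjusted p = 0.0621 with an estimated correlation). High against low dose, inside 1 set, repeated these patterns with 2714 genes called, 1315 higher and 1399 lower. CYP1A1 differed by 4.35 ± 0.13 (adjusted p = 7.25e-32) and NOX1 by -1.96 ± 0.10 (adjusted p = 2.03e-21), and 18 of 18 cholesterol genes were higher (18 adjusted over the list alone, camera adjusted p = 1.51e-30) while 17 of 21 interferon genes were lower (18 adjusted over the list alone, camera adjusted p = 3.97e-15).

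CYP1A1 and CYP1B1 peaked at the medium dose of Scutellariae Radix, not at the high dose. With 100 µg/mL CYP1A1 rose 279-fold to 159 ± 7.54 CPM (log2 change 8.12 ± 0.15, adjusted p = 2.32e-40) and CYP1B1 9.41-fold (3.24, adjusted p = 1.53e-33), and ALDH1A3, which makes retinoic acid, rose 5.70-fold (2.51 ± 0.07, adjusted p = 2.85e-32). High against medium put CYP1A1 at -1.48 ± 0.09 (adjusted p = 3.91e-18) and CYP1B1 at -0.68 ± 0.08 (adjusted p = 4.76e-09), while ALDH3A1 (0.36, adjusted p = 0.0054) and the amino-acid carrier SLC7A5 (0.35, adjusted p = 5.69e-06) were higher at the high dose. The medium dose gave 1103 genes, 591 higher and 512 lower, with 538 without vehicle replicate 1 and 608 without its own replicate 1. At that dose 8 of 9 AhR targets rose (9 adjusted over the list alone, camera adjusted p = 5.95e-34) and 15 of 20 NRF2 targets rose (16 adjusted over the list alone, camera adjusted p = 1.11e-30), and interferon genes fell in 6 of 21 cases (14 adjusted over the list alone, camera adjusted p = 7.27e-09; adjusted p = 0.0563 with an estimated correlation). At the low dose CYP1B1 rose 2.27-fold (1.18 ± 0.08, adjusted p = 1.25e-14), CYP1A1 4.89-fold (2.29 ± 0.25, adjusted p = 1.16e-08), ALDH1A3 by 0.80 (adjusted p = 1.34e-10) and TIPARP, an enzyme that restrains AhR, by 0.59 (adjusted p = 5.82e-05), and AhR targets rose in 3 of 9 cases (3 adjusted over the list alone, camera adjusted p = 3.14e-06). The low dose gave 21 genes, 20 higher and 1 lower, with 9 without vehicle replicate 1 and 10 without its own replicate 2. Without the low-count filter it gave 386, of which 42.7% were higher. A fit of the 6 libraries alone called 6, of which 50% were higher. TIPARP was lost in a fit of the 6 libraries alone (adjusted p = 0.14, the highest over all alternatives). High against medium gave 845 genes (408 higher, 437 lower) and medium against low 556.

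**Figure D2:**
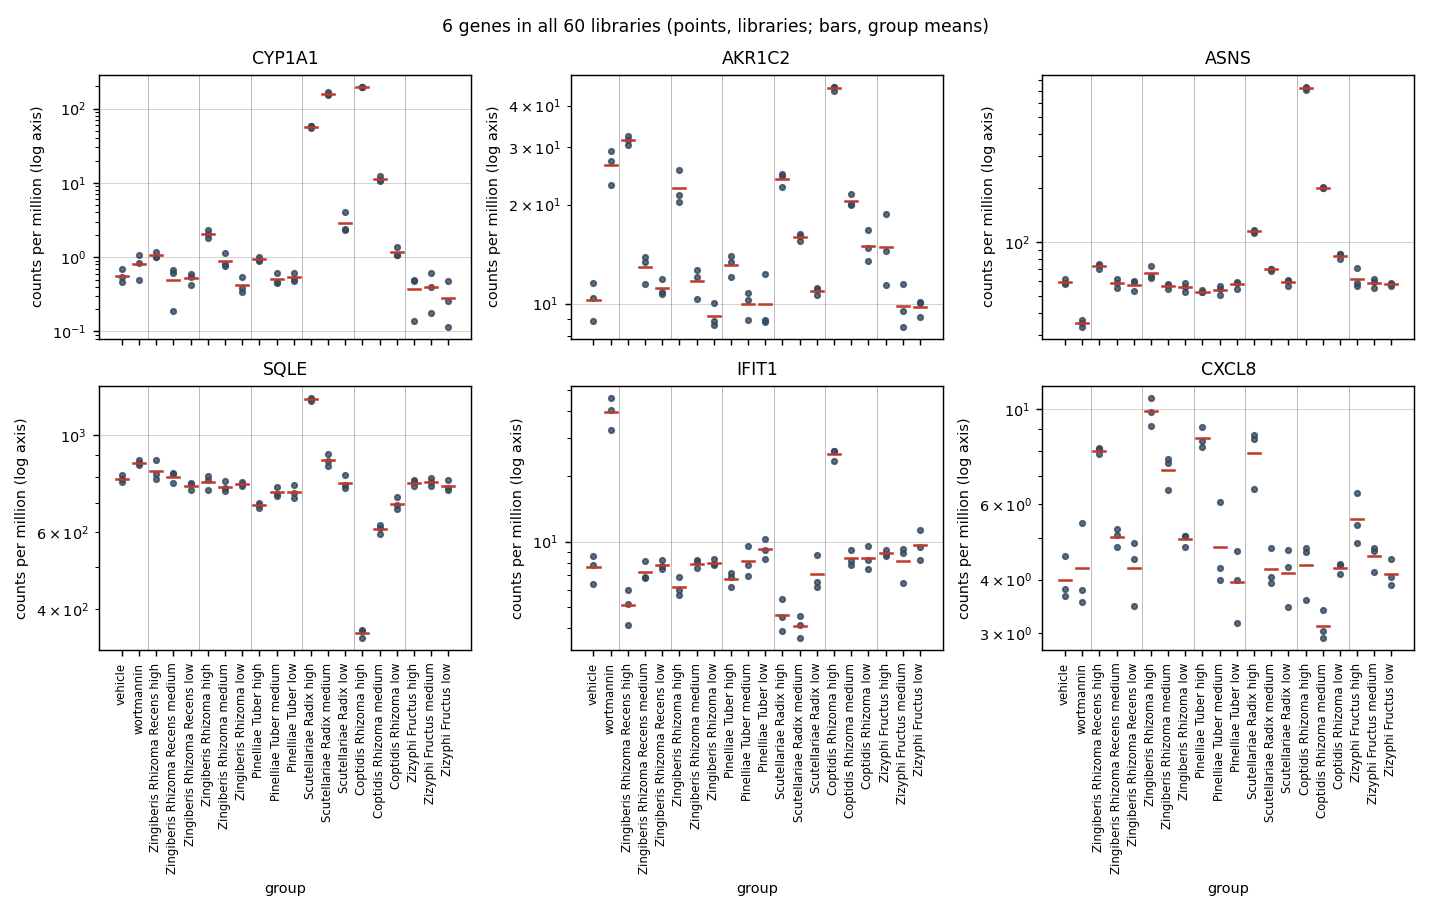
CPM of CYP1A1, AKR1C2, ASNS, SQLE, IFIT1 and CXCL8 in all groups on a log axis. Points are libraries and bars are group means (n = 3).

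Coptidis Rhizoma at the high dose changed more genes than any other treatment. CYP1A1 rose 344-fold. ASNS and CHAC1, which degrades glutathione, both targets of ATF4, rose 12.2-fold and 34.2-fold, and LAMP3, a lysosomal protein, rose 56.6-fold. Genes of sterol synthesis (SQLE and HMGCS1) and the sterol regulator INSIG1 fell. So did MCM4, part of the helicase that opens DNA for replication, and the mucin MUC2. Messages of the mitochondrial genome fell, among them MT-CO1, a subunit of cytochrome oxidase, and MX1 rose. ASNS (ENSG00000070669, chromosome 7: 97852118-97872542) went from 59.6 to 726 CPM (log2 change 3.61 ± 0.06, adjusted p = 4.11e-42), and SQLE (ENSG00000104549, chromosome 8: 124998497-125022283) from 795 to 353 CPM (-1.17 ± 0.04, adjusted p = 1.93e-30). The log2 changes were 8.43 ± 0.15 for CYP1A1 (adjusted p = 1.7e-41), 5.10 ± 0.14 for CHAC1 (adjusted p = 4.85e-34), 5.82 ± 0.29 for LAMP3 (adjusted p = 2.97e-23), -1.11 ± 0.04 for MCM4 (adjusted p = 3.85e-29), -1.88 ± 0.09 for MT-CO1 (adjusted p = 7.2e-25) and 2.19 ± 0.14 for MX1 (adjusted p = 4.74e-19). MUC2 fell by 2.52 (adjusted p = 9.54e-13). In total 8930 genes were called, 4422 higher (818 by at least a doubling) and 4508 lower (787 by at least a halving).

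By list, the high dose of Coptidis Rhizoma raised 21 of 23 ATF4 targets and lowered 1 (21 and 2 adjusted over the list alone, camera adjusted p = 9.76e-27, and 7.11e-06 with an estimated correlation). All 9 AhR targets rose (9 adjusted over the list alone, camera adjusted p = 3.17e-10), with 18 of 20 NRF2 targets while 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 3.41e-15). All 18 cholesterol genes fell (18 adjusted over the list alone, camera adjusted p = 5.87e-19, and 3.01e-05 with an estimated correlation), all 22 DNA replication genes fell (22 adjusted over the list alone, camera adjusted p = 4.99e-17, and 0.000333 with an estimated correlation) and 20 of 21 mitosis genes fell (20 adjusted over the list alone, camera adjusted p = 7.76e-08; adjusted p = 0.0203 with an estimated correlation). All 21 interferon genes rose (21 adjusted over the list alone, camera adjusted p = 7.7e-13; adjusted p = 0.0141 with an estimated correlation). Goblet-cell genes fell in 9 of 12 cases (9 adjusted over the list alone, camera adjusted p = 3.29e-05, and 0.000478 with an estimated correlation), and all 13 mitochondrially encoded messages fell (13 adjusted over the list alone, camera adjusted p = 3.91e-12; adjusted p = 0.0158 with an estimated correlation). NF-kB targets rose in 11 of 17 cases and fell in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00192; adjusted p = 0.0143 with an estimated correlation). Chaperones of the endoplasmic reticulum went both ways, HERPUD1 up by 1.69 and PDIA4 down by 0.83, and the list was not called (7 higher and 8 lower of 16, camera adjusted p = 0.942). High against low dose gave 8694 genes, 4499 higher and 4195 lower. CYP1A1 differed by 7.40 ± 0.14 (adjusted p = 3.29e-41), with 21 ATF4 targets higher (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.45e-27) and 18 cholesterol genes lower (18 adjusted over the list alone, camera adjusted p = 1.71e-17).

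At its lower doses Coptidis Rhizoma raised the ribosomal RNAs of the mitochondrion while lowering most messages of the same genome. MT-RNR1, the small ribosomal RNA, rose 21.2-fold at the medium dose and 11.9-fold at the low dose. MT-RNR2, the large one, also rose, and MT-CO1, MT-CO3 and MT-ND4, which encode respiratory subunits, fell. ASNS and CHAC1 rose at both doses, and TXNIP fell at both. MT-RNR1 (ENSG00000211459, mitochondrial genome 648-1601) stood at 1364 ± 87.1 CPM with vehicle, 28936 ± 987 at the medium dose (log2 change 4.41 ± 0.09, adjusted p = 4.7e-38), 16235 ± 500 at the low dose (3.57 ± 0.09, adjusted p = 1.55e-34) and 2524 at the high dose (0.89 ± 0.08, adjusted p = 2.6e-13). MT-RNR2 changed by 2.82 ± 0.08 and 2.50 ± 0.08 at the medium and low doses (adjusted p = 3.11e-32 and 4.12e-30), and by 0.07 at the high dose (adjusted p = 0.441). At the medium dose MT-CO1 fell by 1.23 (adjusted p = 1.62e-16) and MT-ND4 by 1.56 ± 0.14 (adjusted p = 9.06e-12). At the low dose MT-CO3 fell by 1.72 ± 0.12 (adjusted p = 2.03e-15) and MT-ND4 by 1.91 (adjusted p = 7.82e-14), while MT-ND5 rose with 0.91. Ribosomal RNA made up 10% of counts at the medium dose and 7.55% at the low dose, against 1.19% with vehicle. Messages of the mitochondrial genome fell in 12 of 13 cases at the medium dose (13 adjusted over the list alone, camera adjusted p = 3.46e-34, and 5.02e-05 with an estimated correlation) and in 9 of 13 at the low dose, where 1 rose (9 and 4 adjusted over the list alone, camera adjusted p = 9.9e-22, and 0.00212 with an estimated correlation). MT-ND4L overlaps MT-ND4, MT-ATP8 overlaps MT-ATP6, and nuclear copies such as MTND2P28 and MTND4P12 are near-identical to mitochondrial genes, so those levels are uncertain.

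**Figure D3:**
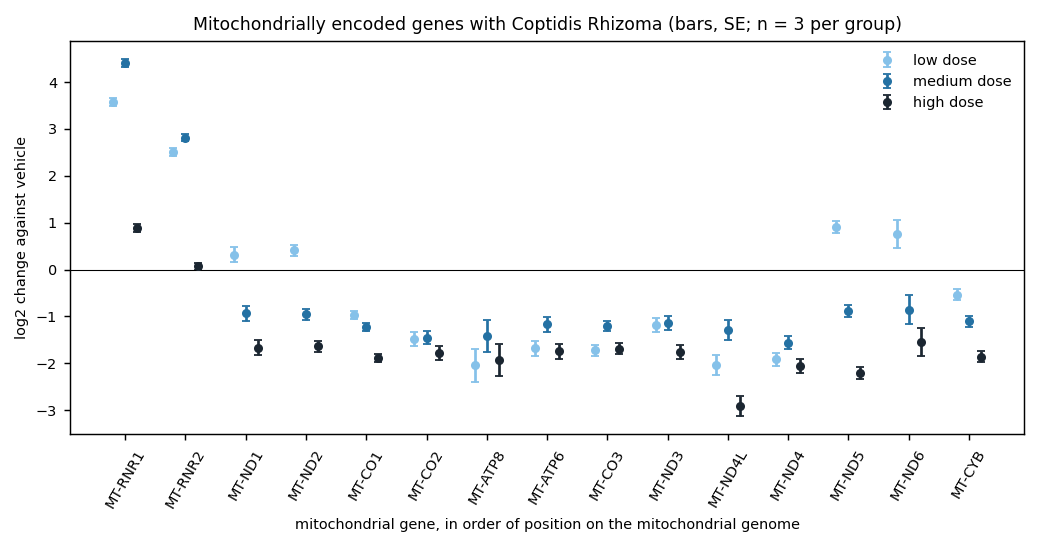
Log2 change against vehicle (± approximate SE) of genes of the mitochondrial genome, in genome order. Shown are the 3 doses of Coptidis Rhizoma (n = 3 libraries per group).

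Apart from the mitochondrial genes, the medium dose of Coptidis Rhizoma raised ASNS by 1.76 ± 0.06 (adjusted p = 7.81e-29), CHAC1 by 2.92 (adjusted p = 5.88e-22) and CYP1A1 19.9-fold (4.31 ± 0.19, adjusted p = 4.5e-24), and lowered SQLE by 0.38 (adjusted p = 1.13e-10). ATF4 targets rose in 17 of 23 cases and fell in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 2.77e-45, and 2e-08 with an estimated correlation), and cholesterol genes fell in 17 of 18 (18 adjusted over the list alone, camera adjusted p = 5.98e-26). Of 1049 genes called, 603 were higher and 446 lower, with 616 without vehicle replicate 1 and 663 and 606 without replicates 1 and 3 of the dose. At the low dose ASNS rose with 0.49 (adjusted p = 1.04e-07), CHAC1 with 1.08 (adjusted p = 1.74e-05) and CYP1B1 with 0.75 (adjusted p = 9.63e-09). ATF4 targets rose in 5 cases (8 adjusted over the list alone, camera adjusted p = 4.24e-08; adjusted p = 0.0165 with an estimated correlation), and NRF2 targets in 3 of 20 (6 adjusted over the list alone, camera adjusted p = 5.06e-06; adjusted p = 0.0524 with an estimated correlation). The low dose gave 66 genes, 37 higher and 29 lower, with 33 and 42 without vehicle replicates 1 and 2 and 43 and 34 without its own replicates 1 and 3. TXNIP fell by 1.44 ± 0.06 at the medium dose (adjusted p = 3.16e-24) and by 0.88 ± 0.06 at the low dose (adjusted p = 5.31e-16), but at the high dose it rose with 1.37. High against medium gave 7730 genes and medium against low 217.

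With Zizyphi Fructus edgeR called few genes, and of the 8 that differed between its high and low doses 7 were NRF2 targets. The number depended on the fit: 4053 genes had an unadjusted p under 0.05 between these doses, and DESeq2 called 1185. Against the low dose, the high dose had more AKR1B10, GCLM, the regulatory subunit of glutathione synthesis, ALDH3A1 and the quinone reductase NQO1. AKR1B10 was at 137 ± 22.9 against 97.1 ± 6.81 CPM (log2 difference 0.50 ± 0.07, adjusted p = 8.26e-05), and GCLM (ENSG00000023909, chromosome 1: 93885205-93909456) differed by 0.39 (adjusted p = 0.000725). ALDH3A1 (0.59, adjusted p = 0.00131) and NQO1 (0.34, adjusted p = 0.00227) were lost without high replicate 3, a library that stood apart (adjusted p = 0.168 and 0.334), and AKR1C3 went from 0.75 (adjusted p = 0.0472) to 0.36 (adjusted p = 1). AKR1C3 was also lost without low replicate 1, 2 or 3 (0.21, 0.132 and 0.0858) and with the replicate block (0.0636). In a fit of the 6 libraries alone 0 of the 8 genes were called (adjusted p = 0.679 for AKR1B10, GCLM, ALDH3A1 and NQO1). All 8 genes called were higher, and NRF2 targets were higher in 7 of 20 cases (18 adjusted over the list alone, camera adjusted p = 2.14e-17, and 0.000807 with an estimated correlation). This count moved to 4376, 1603 and 2 without high replicates 1, 2 and 3, and to 4, 4 and 5 without low replicates 1, 2 and 3. High against medium gave 5 genes and medium against low 0.

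Against vehicle, the high dose of Zizyphi Fructus gave 3 genes, all higher: GCLM (0.34 ± 0.06, adjusted p = 0.0132), the potassium-channel subunit KCNE3 (0.26 ± 0.05, adjusted p = 0.0132) and ME1, which supplies NADPH (0.28 ± 0.05, adjusted p = 0.0184). All 3 were lost without vehicle replicate 2 (adjusted p = 0.233, 0.215 and 0.346) and without replicate 3 of the dose (0.0811, 0.0811 and 0.239; lowest over all alternatives 0.000133, 6.85e-05 and 0.000195). ME1 was also lost without vehicle replicate 1 (0.0577) and KCNE3 without vehicle replicate 3 (0.137), GCLM and ME1 without the 4 libraries that stand apart (0.121 and 0.494), and all 3 in a fit of the 6 libraries alone (adjusted p = 1). The count was 0 without vehicle replicate 2, and 17 and 1 without its own replicates 1 and 3. NRF2 targets rose as a list (2 of 20 genes, 12 adjusted over the list alone, camera adjusted p = 1.1e-21, and 0.000136 with an estimated correlation). At the medium dose edgeR called 0 genes (3507 at unadjusted p under 0.05; 335 by DESeq2, 1481 by edgeR without the low-count filter), and 4 without vehicle replicate 2 or its own replicate 3. At the low dose KCNE3 rose (0.28 ± 0.05, adjusted p = 0.0061) and SLC2A1 fell by 0.18 ± 0.04 (adjusted p = 0.0378; 0.062 with the DESeq2 size factors, and 6.54e-06 to 0.728 over all alternatives). SLC2A1 was lost without vehicle replicates 1, 2 and 3 (0.728, 0.116 and 0.0621), its own replicates 2 and 3 (0.274 and 0.122) and the low-count filter (0.137), and KCNE3 in a fit of the 6 libraries alone (0.171). The low count of 2 became 1, 1 and 4 without vehicle replicates 1, 2 and 3, and 1 without its own replicate 2. Nuclear genes of oxidative phosphorylation were lower as a list (0 genes, 15 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.64e-08; adjusted p = 0.369 with an estimated correlation).

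Across extracts, the high-against-low differences were set side by side, because these share no vehicle library. Over genes called in either extract, fresh ginger and ginger had a correlation of 0.482, with AKR1C2, AKR1B10 and ALDH3A1 among 55 genes higher in both (1.04 from chance), 15 lower in both (0.385) and 0 opposite. Fresh ginger and Scutellariae Radix had 0.569, ginger and Scutellariae Radix 0.569, fresh ginger and Coptidis Rhizoma 0.134, ginger and Coptidis Rhizoma 0.065, and Scutellariae Radix and Coptidis Rhizoma 0.234. Over all genes these pairs had 0.007, 0.167, 0.120, 0.029, 0.023 and 0.129. The sign for the gingers was open, as it ranged from -0.042 without fresh ginger low replicate 2 to 0.115 without fresh ginger low replicate 1, and so was that for ginger and Coptidis Rhizoma (-0.029 without Coptidis Rhizoma high replicate 1). Genes are not independent replicates, so these values carry no p-value. Scutellariae Radix and Coptidis Rhizoma shared 614 higher genes (356 from chance) and 600 lower genes (353), but 707 went in opposite directions (711). Among programs that parted, cholesterol genes such as SQLE rose with Scutellariae Radix and fell with Coptidis Rhizoma, and interferon genes such as MX1 fell with the former and rose with the latter. A test of the difference between the extracts called 18 of 18 cholesterol genes and 21 of 21 interferon genes (high against low dose). For these pairs, the restriction to extracts with more than 100 genes called was chosen after seeing the data.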

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

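The tests in this part, of differences between doses and between extracts, were chosen only after the data were seen.

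Some genes went opposite ways against vehicle at 2 doses of the same extract, and the difference between the doses was itself called by edgeR. For Scutellariae Radix there were 6 such genes between the high and medium doses, beside 932 that went the same way at both. For Coptidis Rhizoma there were 34 between high and medium (892 the same way), 6 between high and low (55 the same way) and 2 between medium and low (61 the same way). TXNIP, a brake on glucose uptake, and its relative ARRDC4 differed most between the high and medium doses of Coptidis Rhizoma among these genes: TXNIP changed by 1.37 at the high, -1.44 at the medium and -0.88 at the low dose (high against medium 2.81 ± 0.06, adjusted p = 3.95e-37), and ARRDC4 rose at the high dose and changed by -1.10 and -0.85 at the others. The skin-barrier gene SCEL changed by 1.01, -0.51 and -0.57. MT-ND5, which differed most between the high and low doses, changed by -2.20, -0.89 and 0.91, and its direction at the low dose opposed that of MT-CO3 and MT-ND4. No explanation was tested for these reversals.

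The change from low to high dose also differed between extracts, by an interaction test for each pair. Fresh ginger differed from Pinelliae Tuber in 15 genes, from Scutellariae Radix in 589, from Coptidis Rhizoma in 6232 and from Zizyphi Fructus in 21. Ginger differed from Pinelliae Tuber in 6 genes, from Scutellariae Radix in 708 and from Coptidis Rhizoma in 6559. Pinelliae Tuber differed from Scutellariae Radix in 1046, from Coptidis Rhizoma in 6398 and from Zizyphi Fructus in 1. Zizyphi Fructus differed from Scutellariae Radix in 1553 and from Coptidis Rhizoma in 6880. For fresh ginger against ginger and for ginger against Zizyphi Fructus edgeR called 0 genes. There were 2346 and 757 at unadjusted p under 0.05, where 830 are expected by chance over 16609 genes. DESeq2 was not run for these tests. Extracts in different sets are compared here, but each change is taken inside its own set.

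Scutellariae Radix and Coptidis Rhizoma differed in 6442 genes, and whole programs parted. Cholesterol genes were higher in 18 of 18 cases with Scutellariae Radix and lower in 18 of 18 with Coptidis Rhizoma, all 18 differing by the interaction test. CYP51A1, a demethylase of sterol synthesis, changed by 0.63 and -0.38 (difference 1.01 ± 0.05, adjusted p = 2.64e-21). Interferon genes were lower in 17 and higher in 21 of 21 cases (21 differing). DNA replication genes were higher in 7 and lower in 2 cases with Scutellariae Radix and lower in 21 with Coptidis Rhizoma (21 differing), and mitosis genes 2 and 2 against 19 lower (18 differing). ATF4 targets were higher in 16 cases and lower in 1 (ALDH1L2, a mitochondrial folate enzyme) with Scutellariae Radix and higher in 21 with Coptidis Rhizoma (21 differing). GCLC rose with both (0.93 and 1.18, adjusted p of the difference = 0.0021).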

How the results depend on the processing

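The alternative without 4 libraries and the leaving out of single libraries for similarity were chosen only after the data were seen.

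The counts of wortmannin, Scutellariae Radix high and Coptidis Rhizoma high against vehicle, and of Coptidis Rhizoma high against low, stayed within 1.5 times under the alternatives run, except wortmannin without vehicle replicate 1. The rule for naming genes gave 1001 gene results to check, more than are reported here. Of these, 990 stayed on their side of the threshold and in direction with the DESeq2 size factors and 915 with no filter. With the DESeq2 test it was 979 of 989, with only the libraries compared 759 of 993, with the replicate block 997 and without the 4 libraries 898. Results without an adjusted p in a fit were left out of the 989 and the 993. With single libraries left out it was 5226 of 6006, with 779 no longer called. SLC7A5 between the gingers at the high dose, not called (-0.071), turned to 0.006 without the 4 libraries and ranged from -0.143 to 0.004 with single libraries out. No scaling moved the median of all genes by more than 0.011. Where a group was left with 2 libraries, the spread was pooled over all groups. Depth and 3 libraries per group limit small changes. Except where fewer libraries or genes explain a change, the cause was not tested.

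No filter on low counts: fresh ginger high 1127, medium 407, low 117; ginger high 244, medium 707, low 602. Pinelliae Tuber high 637, medium 375, low 281; Scutellariae Radix low 386; Coptidis Rhizoma low 465. Zizyphi Fructus high 98, medium 1481, low 1374. High against low: fresh ginger 565, ginger 433, Pinelliae Tuber 90, Zizyphi Fructus 2023. Ginger against fresh ginger 159, 55 and 229 at high, medium and low dose. In the following the majority turned from higher to lower. The share higher was: fresh ginger high 38.8%, ginger high 46.3%, medium 35.8%, Pinelliae Tuber high 37.2%, medium 36.5%, low 43.1%. It was also: Scutellariae Radix medium 48.7%, low 42.7%, Coptidis Rhizoma medium 48.5%, low 44.1%. High against low: fresh ginger 42.5%, ginger 48.3%, Coptidis Rhizoma 49.9%. The cause was not tested.

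DESeq2 test: fresh ginger high 547, ginger medium 12 and low 1, Pinelliae Tuber high 69, medium 16, low 19, Scutellariae Radix low 49, Zizyphi Fructus high 12, medium 335, low 99, and Zizyphi Fructus high against low 1185. With the DESeq2 size factors, Zizyphi Fructus low gave 1.

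Only the libraries compared (6 libraries, so a spread estimated from fewer): fresh ginger high 74, ginger high 10 and medium 1, Pinelliae Tuber high 9, medium 2, low 0, Scutellariae Radix medium 357 and low 6, Coptidis Rhizoma medium 489 and low 25, Zizyphi Fructus high 0, medium 2, low 4. High against low: fresh ginger 23, ginger 34, Scutellariae Radix 4139, Zizyphi Fructus 0. Linear trend on log10 dose: fresh ginger 32, ginger 54, Zizyphi Fructus 0.

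Replicate block: ginger medium 10, Pinelliae Tuber high 47 and low 7, Scutellariae Radix low 35, Zizyphi Fructus medium 1, Zizyphi Fructus high against low 5, and ginger against fresh ginger 1 at the high and 1 at the medium dose. The other counts were within 1.5 times.

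Without the 4 libraries that stand apart: fresh ginger low 1, ginger high 75 and medium 1, Pinelliae Tuber medium 0 and low 0, Zizyphi Fructus medium 2 and low 1, high against low Pinelliae Tuber 15 and Zizyphi Fructus 3, and ginger against fresh ginger high 4. Similarity over all genes became 0.094 (fresh ginger and ginger), 0.125 (fresh ginger and Scutellariae Radix), 0.049 (fresh ginger and Coptidis Rhizoma) and -0.020 (ginger and Coptidis Rhizoma). Part of this follows from fewer libraries.

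With single libraries left out, the counts against vehicle ranged over: wortmannin 2114 to 3297, fresh ginger high 128 to 459 and low 0 to 1, ginger high 66 to 93 and medium 0 to 3, Pinelliae Tuber high 12 to 55, medium 0 to 14, low 0 to 10, Scutellariae Radix medium 538 to 1238 and low 9 to 27, Coptidis Rhizoma medium 606 to 884 and low 33 to 55, Zizyphi Fructus high 0 to 17, medium 0 to 4, low 1 to 4. High against low: fresh ginger 118 to 1305, ginger 63 to 158, Zizyphi Fructus 2 to 4376. Ginger against fresh ginger low: 0 to 358. Similarity: fresh ginger with ginger -0.042 to 0.115, with Scutellariae Radix 0.115 to 0.191 and with Coptidis Rhizoma 0.009 to 0.059; ginger with Scutellariae Radix 0.092 to 0.155 and with Coptidis Rhizoma -0.029 to 0.049; Scutellariae Radix with Coptidis Rhizoma 0.101 to 0.149.

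Of 868 list tests 275 were called, and 105 of these also with an estimated correlation, which is larger than the preset one in lists whose genes move together. With the DESeq2 size factors 272 were the same, with the replicate block 273 and without the 4 libraries 245. Similarity over genes called in either extract was 0.482 (fresh ginger and ginger), 0.569 (fresh ginger and Scutellariae Radix), 0.134 (fresh ginger and Coptidis Rhizoma), 0.569 (ginger and Scutellariae Radix), 0.065 (ginger and Coptidis Rhizoma) and 0.234 (Scutellariae Radix and Coptidis Rhizoma), higher than over all genes. Choosing genes by their calls can itself raise a correlation, and the cause was not tested.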

Other observations

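Of the tests below, those on the mitochondrial RNAs, on the interferon genes, on the share of the size kept and on sets were chosen only after the result was seen; the count of genes called again without 4 libraries and the splits were set before.

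Coptidis Rhizoma at the high dose raised some genes of autophagy and stress arrest and lowered others, and neither list was called. MAP1LC3B, the marker of autophagosomes, rose 3.45-fold (log2 change 1.79 ± 0.05, adjusted p = 4.72e-32) and the autophagy receptor SQSTM1 2.11-fold (1.07 ± 0.06, adjusted p = 1.36e-21). The cell-cycle inhibitor CDKN1A rose 3.30-fold (adjusted p = 4.65e-25) and the stress cytokine GDF15 4.31-fold (adjusted p = 1.55e-21), while BTG2, another p53 target that restrains growth, fell (adjusted p = 1.96e-17). Of 22 lysosome and autophagy genes 10 rose and 7 fell (10 and 7 adjusted over the list alone, camera adjusted p = 0.0645), and of 16 p53 targets 7 rose and 6 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.293). DDIT4, which restrains mTOR, rose by 3.76 ± 0.08 (adjusted p = 2.25e-38). The angiogenic factor VEGFA rose 5.28-fold (adjusted p = 1.16e-38).

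Wortmannin raised VIL1, a protein of the enterocyte brush border, by 0.43 ± 0.04 (adjusted p = 4.13e-12), the stem-cell marker PROM1 by 0.42 (adjusted p = 3.8e-08) and the drug oxidase CYP3A5 by 0.55 (adjusted p = 6.07e-14). ZFAS1, a host of small nucleolar RNAs, rose by 0.68 (adjusted p = 1.17e-07). The aldo-keto reductases AKR1C1 and AKR1C2 rose by 1.21 and 1.38 (adjusted p = 1.07e-13 and 4.93e-13), as with the gingers. LYZ, a leukocyte marker that these cells also express, rose from 1825 to 2400 CPM (adjusted p = 6.71e-07).

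With Coptidis Rhizoma at the low and medium doses the mitochondrial ribosomal RNAs rose and most messages fell (12 of 13 at the medium dose, 9 of 13 at the low dose, where MT-ND5 rose). Handling as a set, if the codes mark it, would reach Zizyphi Fructus of the same set, where the greatest MT-RNR1 change over 3 doses was 0.007. A single scaling factor per library would move all mitochondrial genes alike, but at the low dose MT-RNR1 lay 4.750 above the median of the messages. Carry-over of RNA without a poly(A) tail stays open: the greater median change of the histone list at these doses was -0.135, but the labels name no poly(A) selection, on which that test rests. No biological explanation was tested.

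With wortmannin all interferon genes tested rose. Vehicle libraries low in these genes would leave no difference from the low-dose groups, but against the mean of those 6 groups the list median was 1.371, with 21 of 21 genes higher (lowest 0.605). RNA from leukocytes is argued against by PTPRC, CD3E, CSF1R and ITGB2 together at 0.15 CPM. Handling of the wortmannin libraries as a set cannot be told apart from the treatment, since by the codes 0 other groups share their set. Inhibition of PI3K may also be the source.

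Vehicle differed from the mean of the 6 low-dose groups in 13 genes, 9 higher and 4 lower in the low-dose groups (2345 at unadjusted p under 0.05), among them EME2, NEAT1 (0.323 ± 0.057, adjusted p = 0.00495) and RGS2 (-0.295 ± 0.062, adjusted p = 0.0313). By the test set before, 2 of the 13 were called again without the 4 libraries that stand apart, MT-RNR1 (adjusted p = 1.74e-06) and MT-RNR2 (0.0158), both driven by Coptidis Rhizoma, so the other calls depended on these libraries or on the number of libraries. After that result a further test was added: the median share of the log2 difference kept was 94% (74.6% to 114%), so calls ended with little change in size, as for EME2 (0.443 ± 0.073, adjusted p = 0.00191, to 0.436, adjusted p = 0.0837). Whether a set effect is the cause cannot be told apart, because by the codes 0 other groups share the vehicle set. A difference in DMSO between vehicle and extracts was not tested and stays open as well, since the labels give no DMSO content for the extracts. Some of the 13 genes were changed by an extract at its low dose. MT-CO3 and MT-CO1 changed by -1.722 and -0.969 with Coptidis Rhizoma. CYP1B1 was called with Scutellariae Radix and with Coptidis Rhizoma (edgeR adjusted p = 1.25e-14 and 9.63e-09). The share kept covers these genes too. Apart from them and the ribosomal RNAs, calls of the 13 genes against vehicle may reflect the vehicle group. Examples are EME2 at all doses of Pinelliae Tuber, RGS2 at its high dose and NEAT1 with ginger at the medium dose.

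Each comparison was repeated for all 10 splits of its 6 libraries, which are too few for a share under 0.05. As many genes as in the real split were called by 1 of 10 splits (the real one) for wortmannin (3414), fresh ginger high (347), ginger high and medium (131 and 2), Pinelliae Tuber high and low (31 and 2), Scutellariae Radix high, medium and low (3377, 1103 and 21), Coptidis Rhizoma medium and low (1049 and 66) and Zizyphi Fructus low (2), and for high against low Pinelliae Tuber (7), Scutellariae Radix (2714) and Coptidis Rhizoma (8694), the highest other split giving 0. It was also 1 of 10 for Pinelliae Tuber medium (8), Coptidis Rhizoma high (8930) and ginger high against low (152), the highest other giving 1. For comparisons with 0 genes all 10 splits gave as many: fresh ginger medium (highest other 0) and low (442), ginger low (0), Zizyphi Fructus medium (0), and ginger against fresh ginger high (1), medium (0) and low (948). Fresh ginger high against low had 2 of 10 (297, highest other 749), Zizyphi Fructus high against vehicle 4 of 10 (3, highest other 4138) and high against low 3 of 10 (8, highest other 1706). The splits with many times the real count point to a structure of the samples, and the 3 that called 4138, 3680 and 3202 genes put vehicle replicate 1 together with Zizyphi Fructus high replicate 3, though a further split that did so, with high replicate 1, called 0. The count for Zizyphi Fructus high against vehicle was 3 with the replicate block.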
